A study of Caenorhabditis elegans with 8 samples.

How the data were processed

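Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on Caenorhabditis elegans embryos with an antibody against AMA-1, the largest subunit of RNA polymerase II. The samples comprised 8 libraries. Of these, 4 were AMA-1 ChIP libraries and 4 were input libraries, in each case 2 from embryos given the L4440 control RNAi vector and 2 from embryos with sig-7 RNAi. Per the labels, embryos ranged from the 1-cell to the 350-cell stage, were fixed with formaldehyde and were sonicated. The labels do not say whether the replicates came from separate cultures.

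The deposited values are a 0 or 1 call per gene and condition, a category rather than a measured signal or count. Per the file headers, peaks were called with MACS2 in broad mode at a cutoff of 0.01. Per the file headers, a gene was assigned to a peak when they overlapped by at least 250 bp or 45% of the length of the gene. A call of 1 means such an overlap in both replicates of the condition, and 0 means an overlap in at most 1 of them, also per the file headers. Bowtie 1.0.1 and the genome build ce10 are named in the submitters' processing notes. The MACS2 version, the use of the input libraries in peak calling and the gene annotation are not given in the sources used here. The table holds no read counts, peak heights, coordinates or values per library. The depth is therefore unknown, no error between replicates could be computed, and no statement about the amount of RNA polymerase II at a gene can be made. A call can change when a single replicate crosses the peak threshold, and a long or broad peak can call several adjacent genes. These rules can move the calls of short genes and of genes nested in others more than those of isolated genes.

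The table lists 8922 genes by sequence name, and 0 of them had a call of 0 in both conditions. Genes absent from the table are called "not listed" here. Sequence names were matched without regard to case to the locus tags of the RefSeq gene table for assembly WBcel235. This matched 8824 names and left 98 unmatched. Since that assembly is not the build of the calls, the table was used only for gene names, kinds of gene and the order of neighbouring genes. Its coordinates and chromosomes entered only through that order, which was kept within chromosomes, and its gene lengths were not used. Neither the planned chromosome distribution nor the position of peaks within genes was analysed.

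Genes were divided into those called in both conditions, in control only and in sig-7(RNAi) only. The overlap of the 2 call sets was compared with 1000 circular shifts of the sig-7(RNAi) calls along the gene order of each chromosome. Before the data were examined, 18 gene lists were fixed that fit early embryos, their tissues and carry-over from the mothers. Of the listed symbols, 4 were absent from the gene table. The presence of each list in each condition was tested against all other genes of the gene table (46926 genes) with a two-sided Fisher's exact test. The design had foreseen tests on counts or signal per peak, which these calls do not allow. The difference between conditions was therefore tested on genes called in a single condition. A two-sided Fisher's exact test compared the control-only and sig-7(RNAi)-only numbers of a list with those of all other genes. This test was chosen after the form of the table was known. P-values were adjusted by the Benjamini-Hochberg method within each family of lists, with a threshold of 0.05. Since neighbouring genes often share a peak, whole stretches of adjacent genes with the same call were also used as the unit. Their labels were permuted 10000 times. The permutation sets a list against the control-only share of stretches, and Fisher's exact test against that of other genes. Results of the 2 tests can therefore differ by this reference alone. Exact (Clopper-Pearson) 95% intervals accompany shares of genes. All p-values and intervals treat genes or stretches as units. They describe these 2 call sets, each made from 2 libraries, and do not measure variation between embryo samples.

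The test of direction was tested on simulated calls over 19983 protein-coding genes. Fisher's test called 100.0% of 50 lists given a strong lean to control-only calls and 1.0% of 200 lists with no lean. The permutation of stretches called 98.0% and 1.5%. Lists with a lean held 20 genes, each called in a single condition, and lists without one 200 genes of any call. The protein-coding lists held at most 9 genes called in a single condition, and the rates were not measured for lists that small. Members were drawn at random along the gene order, so the rates were not measured for lists of neighbouring genes either. Alternatives were protein-coding genes alone, all genes but piRNA and ncRNA genes, counting each stretch once and permuting stretches. Genes named in the text follow a rule fixed beforehand, namely sig-7, ama-1 and up to 4 called members of each list. As the table holds no values to rank by, list order was used, and further members were named after their calls were seen. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.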

Results

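The genomic location of RNA polymerase II was compared with and without RNAi of sig-7, which encodes a nuclear cyclophilin with an RNA recognition motif. For this, early embryos of strain KW2309 were subjected to AMA-1 ChIP-seq. Control embryos received L4440, the empty RNAi vector, and the others sig-7 RNAi. Each condition had 2 ChIP libraries and 2 input libraries. The results are calls per gene, set to 1 when both replicates of a condition had a peak over the gene. The p-values and intervals given for them treat genes or stretches of neighbouring genes as units and contain no replicate error.

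In control embryos 6829 genes were called, and in sig-7(RNAi) embryos 6599. Both sets shared 4506 genes, which was 65.98% of the control set (95% interval 64.8 to 67.1) and 68.3% of the sig-7(RNAi) set (67.1 to 69.4). A further 2323 genes were called in control only and 2093 in sig-7(RNAi) only. ama-1 itself (F36A4.7) was called in both conditions. The gene sig-7 (F39H2.2) was called in sig-7(RNAi) embryos only. A polymerase call at the gene does not give the level of its transcript, so the knockdown cannot be read from it. Among genes in the gene table, 4468 were shared, against a mean of 1269 and a maximum of 1714 in 1000 circular shifts of the calls. This was 3.52-fold above the shifted mean (one-sided permutation p = 0.001, the smallest these shifts can give). Both sets are of the same polymerase in embryos of the same stage range, and the shifts pair calls with other genes. The overlap therefore does not measure an effect of sig-7 RNAi.

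The balance between conditions depended on the kind of gene. Among protein-coding genes, 3360 were called in both conditions, 1204 in control only and 1409 in sig-7(RNAi) only, so that here more genes were specific to sig-7(RNAi). Of the protein-coding genes called in control, 73.6% were also called in sig-7(RNAi) (95% interval 72.3 to 74.9). The surplus of control-only calls in the whole table lay in piRNA genes, with 487 in control only and 181 in sig-7(RNAi) only, and in other ncRNA genes, with 511 and 272. Only 28.2% of the piRNA genes called in control were also called in sig-7(RNAi) (24.8 to 31.7). Pseudogenes leaned the other way, with 36 in control only and 89 in sig-7(RNAi) only. Against all other genes called in a single condition, piRNA, other ncRNA and pseudogenes each differed by Fisher's exact test (adjusted p = 3.4e-30, 7.9e-15 and 1.1e-07 over 8 kinds of gene). They also differed in a permutation test on whole stretches of neighbours (adjusted p = 0.0011, 0.0008 and 0.0011). Protein-coding genes passed Fisher's exact test (adjusted p = 1.9e-25) but not the permutation of stretches (0.51). miRNA genes, with 15 in control only and 6 in sig-7(RNAi) only, passed the permutation (0.046) but not the exact test (0.12). The reference of the permutation was the control-only share of stretches, 45.6%, and not that of other genes. Over all listed genes the share was 52.6%, and over protein-coding genes 46.1%. Where the permutation and the exact test differ, this reference alone can be the reason, so an effect of neighbouring genes cannot be read from it. For piRNA genes the lean rests on long stretches. Counted once per stretch it was no longer seen, with 80 control-only and 92 sig-7(RNAi)-only stretches. The control-only share of these was 46.5%, against 45.6% of all stretches.

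**Figure D1:**
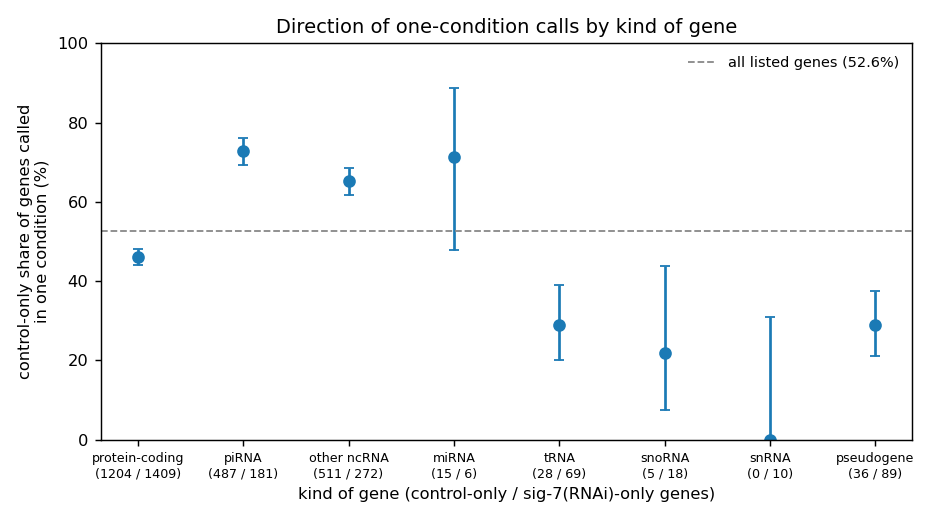
Share of genes called in control only among genes called in a single condition (y axis, percent) for 8 kinds of gene (x axis, with the 2 gene numbers); points are shares, bars exact 95% intervals over genes, and the dashed line is the share in all listed genes, 52.6%. piRNA, other ncRNA and miRNA genes lie above the line, and protein-coding, tRNA, snoRNA, snRNA and pseudogenes below it.

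Most genes of the ribosomal protein, housekeeping and translation factor lists were called in both conditions. Of 78 ribosomal protein genes, 65 were called in both, among them rpl-10L (F10B5.1), rpl-10a (Y71F9AL.13), rpl-11.1 (T22F3.4) and rpl-12 (JC8.3). Another 5, among them rpl-11.2 (F07D10.1), were called in control only, and 4 in sig-7(RNAi) only. All 19 genes of the housekeeping list were called in sig-7(RNAi) and 17 of them in control. These included the actin genes act-1 (T04C12.6), act-2 (T04C12.5) and act-3 (T04C12.4) and the tubulin gene tba-1 (F26E4.8). The translation factor list had 9 of 16 genes in both conditions, including eef-1A.1 (F31E3.5), eef-1A.2 (R03G5.1), eef-1B.2 (Y41E3.10) and eef-1G (F17C11.9). Another 3 of its genes, iff-1 (T05G5.10), ife-3 (B0348.6) and eif-6 (C47B2.5), were called in sig-7(RNAi) only. The 3 lists were over-represented in both conditions by Fisher's exact test (adjusted p from 1.1e-48 to 0.0002 in control and from 5.3e-48 to 1.1e-07 in sig-7(RNAi)). None of the 3 passed the exact test of direction (adjusted p = 1.0 for ribosomal proteins, 0.37 for housekeeping genes and 0.32 for translation factors). For translation factors, the 95% interval of the odds of control-only against sig-7(RNAi)-only calls, relative to other genes, reached from 0 to 2.18.

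Histone and heat shock genes were also mostly called in both conditions. Of 80 histone genes, 54 were called in both conditions, including his-1 (T10C6.14) and his-2 (T10C6.13), 1 in control only (hil-7, C01B10.5) and 1 in sig-7(RNAi) only (hil-4, C18G1.5). Of the histone genes called in control, 98.2% were called in sig-7(RNAi) (90.3 to 99.95). Of 19 heat shock genes, 17 were called in both conditions and 0 in a single one. They included the chaperone genes hsp-1 (F26D10.3), hsp-3 (C15H9.6), hsp-4 (F43E2.8) and hsp-6 (C37H5.8). The heat-inducible small heat shock genes hsp-16.1 (T27E4.8) and hsp-16.2 (Y46H3A.3) were likewise called in both. Both lists were over-represented in each condition (adjusted p of 2.2e-12 or lower by Fisher's exact test). Copies of histone and hsp-16 genes are near-identical, so calls of single copies are uncertain.

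In the epidermis, muscle and pharynx and neuron lists, 14 genes were called in control only and 1 in sig-7(RNAi) only. The epidermis list had 6 of 11 genes in control only and 0 in sig-7(RNAi) only. These were the GATA factor genes elt-1 (W09C2.1) and elt-3 (K02B9.4), lin-26 (F18A1.2), which encodes a zinc finger protein needed for epidermal fate, nhr-25 (F11C1.6), the cuticle collagen gene dpy-7 (F46C8.6) and the junction gene ajm-1 (C25A11.4). dlg-1 (C25F6.2), vab-10 (ZK1151.1) and elt-6 (F52C12.5) were called in both. The muscle list had 4 of 13 genes in control only, namely the transcription factor gene unc-120 (D1081.2), the myosin heavy chain genes myo-3 (K12F2.1) and unc-54 (F11C3.3), and the tropomyosin gene lev-11 (Y105E8B.1). Its other called genes, among them the MyoD homologue hlh-1 (B0304.1), were called in both. The pharynx and neuron list had 4 of 13 genes in control only, namely the pharyngeal selector gene pha-4 (F38A6.1), tbx-2 (F21H11.3), hlh-14 (C18A3.8) and cnd-1 (C34E10.7). In this list snb-1 (T10H9.4), which encodes synaptobrevin, was called in sig-7(RNAi) only. None of the 11 intestine genes was listed.

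Taken one list at a time, these splits did not pass the adjusted test. Fisher's exact test gave adjusted p = 0.12 for epidermis (unadjusted 0.032), 0.32 for muscle and 0.52 for pharynx and neuron. The epidermis list passed in a permutation test on stretches of neighbours (adjusted p = 0.047). The reference there was the control-only share of stretches, 45.6%, against 52.6% over all listed genes. The lower p need not come from the treatment of neighbours. With piRNA and ncRNA genes left out of the background, the epidermis list passed Fisher's exact test (adjusted p = 0.039) but not the permutation of stretches (0.062). It did not pass the exact test against protein-coding genes alone (0.10). Epidermis and muscle genes were over-represented in control by Fisher's exact test (adjusted p = 2.2e-06 and 0.0002) and did not pass the test in sig-7(RNAi) (0.23 and 0.12).

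**Figure D2:**
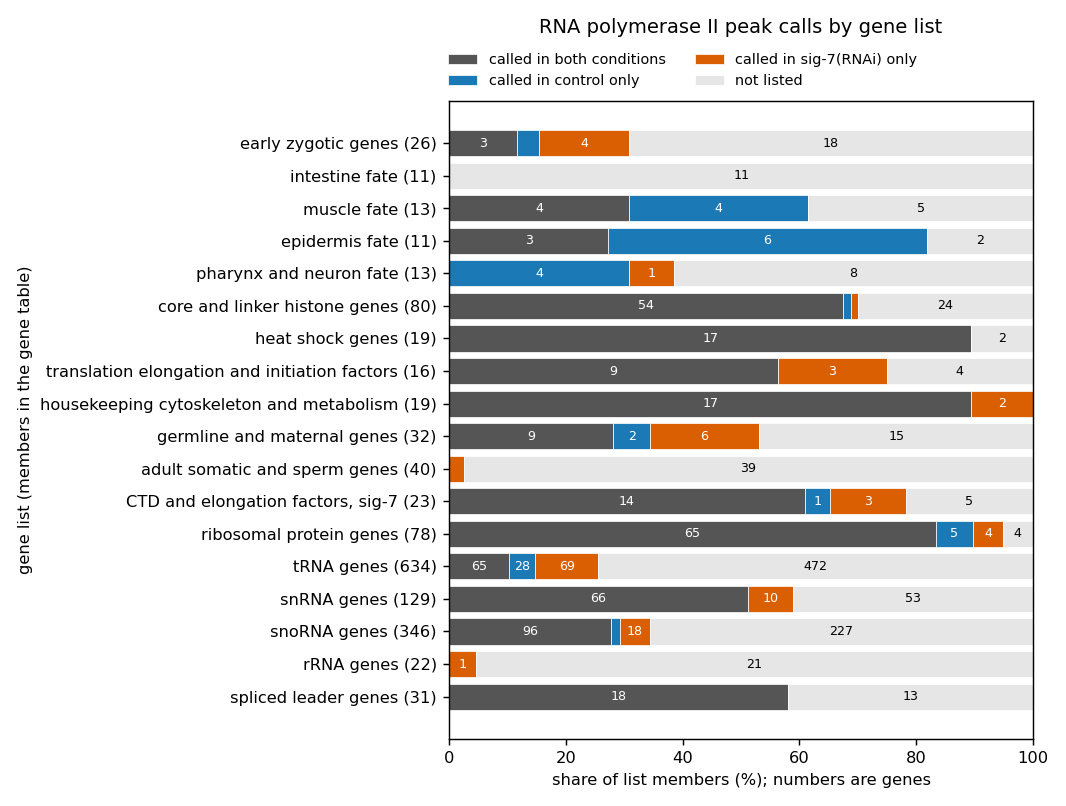
Share of the members of each gene list (x axis, percent; y axis, list and its number of members in the gene table) called in both conditions, in control only, in sig-7(RNAi) only or not listed; numbers in the bars are genes. The muscle, epidermis and pharynx and neuron lists hold 14 control-only genes and 1 sig-7(RNAi)-only gene, whereas ribosomal protein, histone and heat shock genes were mostly called in both.

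Early zygotic and germline genes did not pass the test of direction. Of 26 early zygotic genes, 3 were called in both conditions, namely vet-2 (C35E7.1), nhr-2 (C32F10.6) and pal-1 (C38D4.6). Only ceh-27 (F46F3.1) was called in control only, and 4 were called in sig-7(RNAi) only, namely the endomesoderm gene med-2 (K04C2.6), ceh-51 (Y80D3A.3), tbx-11 (F40H6.4) and vet-6 (F44F1.7). med-2 has a near-identical copy, med-1, which makes its call uncertain. Of 32 germline and maternal genes, 9 were called in both, including pie-1 (Y49E10.14) and pos-1 (F52E1.1), 2 in control only and 6 in sig-7(RNAi) only. The last were mex-1 (W03C9.7), the germline helicase gene glh-1 (T21G5.3), the Notch receptor gene glp-1 (F02A9.6), mes-4 (Y2H9A.1), gld-1 (T23G11.3) and puf-8 (C30G12.7). Fisher's exact test of direction gave adjusted p = 0.37 for early zygotic and 0.34 for germline genes. Of 40 vitellogenin, sperm and cuticle genes, chosen as signs of carry-over from the mothers, 1 was called (vit-1, K09F5.2, in sig-7(RNAi) only). A gene without polymerase gives no call, so carry-over of silent chromatin is not measured here. Most of this list are msp genes, whose copies are near-identical, so their missing calls are uncertain. By Fisher's exact test this list was under-represented in control (adjusted p = 0.0044) and did not pass the test in sig-7(RNAi) (0.055). Against protein-coding genes alone it was under-represented in both conditions (adjusted p = 9.0e-05 in control and 0.0010 in sig-7(RNAi), Fisher's exact test).

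Genes for transcription elongation and modification of the polymerase tail were called in both conditions for 14 of 23 members, including the cyclin T gene cit-1.2 (F44B9.3), the kinase gene cdk-12 (B0285.1), cdk-7 (Y39G10AL.3) and spt-5 (K08E4.1). The kinase gene cdk-9 (H25P06.2) was called in control only. Besides sig-7, cyh-1 (Y49F6B.1) and wdr-5.1 (C14B1.4) were called in sig-7(RNAi) only. The list did not pass the test of direction (adjusted p = 0.52, Fisher's exact test).

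Genes of small structural RNAs leaned to sig-7(RNAi). Of 129 snRNA genes, 66 were called in both conditions, 0 in control only and 10 in sig-7(RNAi) only, among them C05G6.4 and C28A5.7. Of 634 tRNA genes, which are transcribed by RNA polymerase III, 65 were called in both, 28 in control only and 69 in sig-7(RNAi) only. Of 346 snoRNA genes, 96 were called in both, 5 in control only and 18 in sig-7(RNAi) only. Fisher's exact test of direction gave adjusted p = 3.7e-05 for tRNA, 0.0043 for snRNA and 0.015 for snoRNA genes. For tRNA genes the odds of a control-only call were between 0.22 and 0.57 of those of other genes (95% interval). In a permutation test on stretches of neighbours, tRNA and snRNA genes still passed (adjusted p = 0.047 for each) and snoRNA genes did not (0.15). With piRNA and ncRNA genes left out of the background, tRNA and snRNA genes passed Fisher's exact test (0.023 for each) but not the permutation of stretches (0.062 for each). Of the 31 spliced leader genes, 18 were called in both and 0 in a single condition, including sls-2.1 (ZK1248.18) and sls-2.10 (F23B2.14), and 30 of the 31 also belong to the snRNA list. Of 22 rRNA genes, rrn-4.11 (Y102A5D.9) alone was called, in sig-7(RNAi) only. These genes exist in near-identical copies and many lie in or beside protein-coding genes, so a call need not come from the RNA gene itself.

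Calls specific to sig-7(RNAi) lay beside shared genes more often than calls specific to control. Of 1409 protein-coding genes called in sig-7(RNAi) only, 43.2% (95% interval 40.6 to 45.9) had an adjacent protein-coding gene that was called in both conditions. Of 1204 called in control only, 25.2% did (22.8 to 27.8). Control-only genes adjoined another control-only gene in 53.6% of cases (50.7 to 56.4), and sig-7(RNAi)-only genes another sig-7(RNAi)-only gene in 48.9% (46.26 to 51.55). Counted by stretch, 576 of 1007 sig-7(RNAi)-only stretches and 299 of 848 control-only stretches adjoined a shared gene (p = 3.0e-21, two-sided Fisher's exact test). Permuting the labels of the stretches gave p = 0.0001, the smallest that 10000 permutations can give.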

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

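The settings foreseen before the data were examined (normalization, filters, pseudocounts, overlap rules, windows, peak strength and leaving out replicates) were not run, since calls that already combine replicates allow none of them. Those below were all chosen after seeing the data. No paired analysis was possible because the calls merge the replicates of each condition. The ratio of control-only to sig-7(RNAi)-only genes, 1.11 over all listed genes, reversed to 0.855 in protein-coding genes, 0.960 without piRNA genes and 0.808 without piRNA and ncRNA genes. It was 0.839 with each stretch of neighbouring genes counted once and 0.842 with each protein-coding stretch counted once. The share of control genes also called in sig-7(RNAi), 65.98%, became 73.6%, 70.2%, 73.9%, 63.3% and 64.1% under the same 5 settings. The overlap stayed above the circular shifts in protein-coding genes (2.72-fold, permutation p = 0.001). Of the 18 lists, 3 leaned to a single condition (tRNA, snRNA and snoRNA genes). Permuting stretches also gave 3, with epidermis in place of snoRNA genes, as did Fisher's exact test with piRNA and ncRNA genes left out of the background. With both changes together, permutation of stretches gave 0, and 5 lists had an unadjusted p under 0.05. Among the 13 protein-coding lists against protein-coding genes, 0 leaned by Fisher's exact test, and permuting stretches gave 0 too, although epidermis (p = 0.0095) and muscle (p = 0.045) were below 0.05 before adjustment. The histone list, with 1 gene on either side, changed the sign of its log2 direction ratio from -0.15 to 0.23 against protein-coding genes and 0.32 without piRNA and ncRNA genes. Depth is unknown, and a gene with a call of 0 may have had a peak in 1 replicate.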

Other observations

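All tests in this part were chosen after the results were seen, except that of transcription factor classes outside the lists, whose prediction was written first. The classes below group genes by the first part of their names, need not be families of related genes, and include a few genes of the lists above. Of 26 nucleoporin genes (npp), 13 were called in both conditions, 0 in control only and 10 in sig-7(RNAi) only, among them npp-2, npp-5 and npp-8. Of 25 eif genes, 11 were called in both, 1 in control only and 8 in sig-7(RNAi) only. Of 104 F-box genes of the fbxb class, 8 were called in both, 5 in control only and 22 in sig-7(RNAi) only. Of 239 C-type lectin genes (clec), 12 were called in both, 0 in control only and 8 in sig-7(RNAi) only. In the opposite direction, 6 dpy genes, several of which encode cuticle collagens, were called in control only and 0 in sig-7(RNAi) only. The 6 included dpy-3, dpy-10 and dpy-7, which is also in the epidermis list. The arrestin domain genes (arrd) had 5 in control only and 0 in sig-7(RNAi) only, and the nuclear hormone receptor genes (nhr) 13 and 5. None of the 46 name classes tested passed adjustment (lowest adjusted p = 0.078, Fisher's exact test), and these 7 had an unadjusted p under 0.05. The collagen class col was not among the 7, with 7 genes in control only and 5 in sig-7(RNAi) only (unadjusted p = 0.40, Fisher's exact test).

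Chemoreceptor families were largely not listed. Of 220 srh genes, 3 were called in control where 50.2 would follow from the rate over protein-coding genes (adjusted p = 2.1e-18, Fisher's exact test), and of 193 str genes 5 were called in control against 44.1 (adjusted p = 5.7e-14). In sig-7(RNAi), 3 srh and 8 str genes were called.

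Tissue fate genes were called in control only 14 times and in sig-7(RNAi) only 1 time over the 4 fate lists together, and 33.3% of those called in control were kept (95% interval 14.6 to 56.97). Permutation of stretches among protein-coding genes gave p = 0.0003 for the 4 lists, but they were pooled after their values were seen. A random split of calls over stretches is argued against by a permutation that allows for this pooling. It does not allow for the choice of test and background, also made after the data were seen. This permutation set the 4 lists against the most uneven of all 2047 groups of lists in each permutation (p = 0.032). It was run among protein-coding genes only. Fisher's exact test of the pooled lists gave p = 0.00025 among these and 0.0012 among all genes. Nearness to the peak threshold was not measured, since the calls hold no signal. Taken singly, none of the lists passed the permutation among protein-coding genes (lowest adjusted p = 0.10), with epidermis (0.0091) and muscle (0.0425) under 0.05 before adjustment. Among all genes epidermis passed (adjusted p = 0.047, permutation), where the reference is the control-only share of stretches of all kinds of gene. A general shortage of called protein-coding genes in sig-7(RNAi) is argued against by the ratio of control-only to sig-7(RNAi)-only genes, 0.855. The control-only share was 46.1% (44.2 to 48.01). This ratio does not argue against a shortage of isolated peaks. Of the sig-7(RNAi)-only stretches of protein-coding genes, 576 of 1007 (57.2%) adjoined a shared gene, against 299 of 848 control-only stretches (35.3%). Among stretches with no shared gene beside them, control-only ones were therefore the more numerous. A shortage of isolated peaks in sig-7(RNAi) thus stays open for the split of the fate genes and was not tested on them. Younger embryos in the sig-7(RNAi) samples may also give this split. That explanation cannot be told apart from the treatment, since the labels give the same stage range for all samples. Early zygotic and germline or maternal genes together had 3 control-only and 10 sig-7(RNAi)-only genes (p = 0.16, Fisher's exact test). In sig-7(RNAi), 22 of these genes were called against 13.8 expected from all protein-coding genes (p = 0.019, Fisher's exact test, unadjusted). In control, 15 of them were called against 13.25 expected (p = 0.64, Fisher's exact test). The excess in sig-7(RNAi) lay mostly in germline and maternal genes, with 15 called against 7.6 expected (p = 0.0055, Fisher's exact test, unadjusted). Early zygotic genes were near the background in sig-7(RNAi), with 7 called against 6.2 expected. Tests within each condition do not compare the conditions, and the split itself did not pass (p = 0.16, Fisher's exact test). An effect of sig-7 RNAi on tissue genes stays open and was not tested separately.

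A wider effect on developmental regulators was predicted as a hypothesis for homeobox, T-box, GATA, forkhead and Sox genes outside the lists. These had 6 control-only genes, among them ceh-43 and sox-2, and 8 sig-7(RNAi)-only genes, among them tbx-33 and fkh-3 (permutation p = 1.0). The predicted lean was not seen, and the interval of the odds ratio, 0.25 to 2.89, is wide.

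The 487 control-only piRNA genes, 2.69 times the number called in sig-7(RNAi) only, were more concentrated than those. A total of 59.8% of them lay in the 10 fullest of 82 intervals between protein-coding genes, against 33.7% in the 10 fullest of 91 for sig-7(RNAi)-only piRNA genes. A flanking protein-coding gene had the same call for 68.6% of control-only (64.25 to 72.68) and 58.6% of sig-7(RNAi)-only piRNA genes (51.02 to 65.82). Chance in single stretches is argued against by permutation (p = 0.0003). Counted once per stretch, however, piRNA genes gave 80 control-only and 92 sig-7(RNAi)-only stretches, a ratio of 0.870. The control-only share of these stretches, 46.5% (38.9 to 54.3), holds the 45.6% of all stretches in its interval. This is consistent with a few broad peaks covering many piRNA genes in control rather than with many separate piRNA calls, and no biological explanation was tested.

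The gene sig-7 was called in sig-7(RNAi) only, although its transcript was the target. DNA of the feeding plasmid, which carries a piece of the target gene, could add reads there. Of the 8 nearest protein-coding neighbours, 5 were also called in sig-7(RNAi) only (cpn-1, mfap-1, mog-7, syp-3 and F39H2.3), against a median of 1 for all such genes, and 1.56% of them had as many. The 2 adjacent genes did not share the call, however, since syx-17 was called in both conditions and flp-22, like mrt-1 beyond it, was not listed. Plasmid reads at sig-7 therefore cannot be told apart from polymerase without the coverage along the gene.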
